A study of Homo sapiens with 21 samples.

How the data were processed

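The data were gene expression arrays of MCF10A, an immortalised line of non-tumorigenic human mammary epithelial cells. Per the labels' protocols, low-passage cells spent 24 h in medium lacking epidermal growth factor (EGF) and a further 24 h in starvation medium with 1% horse serum, and then received EGF at 20 ng/ml and were harvested before it (0 min) or 20, 40, 60, 120, 240 and 480 min after it. Each time had 3 biological replicates, which the labels describe as triplicate cultures, so the set held 21 arrays in 7 groups, and the number of arrays limits the precision. The set held no untreated arrays at the later times. An effect of EGF therefore cannot be told apart from effects of handling or of time in culture. Per the labels, total RNA was extracted with DNase digestion, ribosomal RNA was removed, and the target was labelled with biotin.

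The deposited table held 1 intensity per probeset and array on a linear scale, for 1384231 probesets. Per the submitters' processing notes, PLIER and Affymetrix Expression Console 1.1 were used. Their role, settings, background correction and probe annotation are not given in the sources used here. The medians of the 21 arrays lay between 20.44 and 20.56 intensity units and their log2 medians differed from the common value by at most 0.004, so the values had been equalised between arrays before deposit, by a method not given in the sources used here. No detection calls were used.

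Probesets were named through the platform annotation of the array. It paired 354600 probesets with 1 gene symbol, 14898 with several symbols, and left 1014733 unnamed here. Of the 19497 symbols of single-gene probesets, 16426 were current in the gene table of assembly GRCh38.p14, 2950 were updated through a unique synonym and 121 were kept as annotated. The reference was used only for names. No gene coordinates are given, because no build is named for the array in the sources used here.

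Intensities were transformed to log2(intensity + 16). A probeset was kept when its mean over all 21 arrays was at or above the median of all probesets, which was 5.18 on this scale, or 20.2 intensity units. This kept 261183 single-gene probesets, 73.7% of them. A gene's value was the median over its kept single-gene probesets, with at least 3 required, so 16614 genes were tested. A log2 change is therefore on the log2(intensity + 16) scale and understates the change of genes with low signal.

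All 21 arrays entered a single linear model with 1 mean per time in limma 3.58.1 (lmFit and eBayes) under R 4.3.3 and the data.table package (1.17.8). The variance had 14 residual and 7.08 prior degrees of freedom, and the median replicate SD of a gene was 0.169 on the log2 scale. Each EGF time was contrasted with 0 min, successive times were contrasted with each other, and a moderated F-test covered the 6 contrasts against 0 min. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. Values after ± in the results are limma's standard errors of a log2 change between 3 and 3 arrays.

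Lists of genes for 21 themes were tested with camera at a preset correlation of 0.01, adjusted over the lists within a time. Each list's members were also counted as higher, lower or not passing, over all genes tested and adjusted over the list alone. The themes were immediate early transcription factors, feedback regulators of ERK and EGFR signalling, regulators of mRNA decay and translation, EGF family ligands and receptors, chemokines with cytokines and NF-kB targets, extracellular proteolysis and migration, SRF and YAP targets of the actin cytoskeleton, ID and BMP targets, and FOXO and quiescence genes. The others were G1 and S phase, G2 and M phase, cholesterol synthesis and uptake, ribosome biogenesis with RNA polymerase I, glycolysis with transport and amino acid supply, p53 targets, interferon response, epithelial to mesenchymal transition factors, basal and squamous markers, luminal markers, fibroblast markers and reference genes. The luminal and fibroblast lists stand for other cell types. The transition factor list mixes epithelial genes such as CDH1 and OVOL1 with mesenchymal ones such as VIM and ZEB1. Some genes stand in more than 1 list, such as GATA3 under ID and BMP targets and luminal markers.

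Lists, tests, thresholds and most alternatives were fixed before the data were examined. Named genes were, per time, the 12 higher and the 12 lower genes with the largest change among called genes whose 3 treated arrays all lay on the same side of the 3 untreated arrays. Up to 4 members of each list with the smallest adjusted p at the time described were added. Members behind a count of 5 or fewer, genes named for the successive intervals and genes named for turning from higher to lower were also named, after their values had been seen.

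The alternatives were quantile normalisation, median centring, pseudocounts of 1 and 64, no filter and a filter at the 75th percentile, the mean of probesets, a trended and robust variance, the replicate letter as a block, only the 6 arrays of the times compared, each array left out, a threshold of 0.01, a change of at least 2-fold, and for lists an estimated correlation and fry. An array index, the median log2 value of single-gene probesets minus that of unnamed probesets, was computed per array. Its use as a covariate, and a fit without the array of each time farthest from its time's mean index, were chosen after seeing the data, as was leaving out each array for the lists. The steps were tested on simulated data made from the 120 min against 0 min comparison of 16614 genes with 200 genes changed. A further list of genes was shifted by 0.5. The fit recovered 44.8% of changes of 0.5, 97% of changes of 1 and 100% of changes of 2 on the log2 scale, and 2.25% of its calls were false. The simulated noise was independent between genes and arrays, while real arrays of the same time differed along a shared axis that held 38.5% of the variation within times. These shares therefore need not hold for the real data.

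A comparison of intronic with exonic signal, which the naming of pre-mRNA and mRNA in the series title invites, was planned. It was not run, since no table used here places probesets in introns. Unnamed probesets and those with several symbols entered no gene value.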

Results

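Gene expression was measured on 21 arrays of MCF10A mammary epithelial cells, 3 per time, before EGF (0 min) and 20, 40, 60, 120, 240 and 480 min after it was added to starved cells. Median intensities of the arrays lay between 20.44 and 20.56, and replicate arrays correlated across genes at between 0.944 and 0.988. Arrays of the same time differed along 1 main axis, which held 38.5% of the variation within times and followed an array index, the median log2 signal of single-gene probesets minus that of unnamed ones. The mean index was 1.24 ± 0.02 (SD, n = 3) at 0 min and between 1.27 and 1.33 at the EGF times. Higher and lower counts of genes are therefore also given with this index as a covariate, an alternative chosen after seeing the data. Values are log2 changes against 0 min unless stated otherwise. For every called list with no second adjusted p the call held with an estimated correlation, at a larger adjusted p than the one printed. Where calls held, adjusted p with an estimated correlation lay between 6.9e-07 and 0.039. The highest count of called lists in another split of the arrays lay between 7 and 10 at each time. The real times gave 10 to 13, so list counts alone decide little.

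The comparisons against 0 min ask which transcripts changed by each time after EGF. Without untreated arrays at the later times, they cannot separate EGF from handling or time in culture. Of 16614 genes tested, 4570 passed the F-test over the 6 contrasts, and the largest change was a rise in 3062 and a fall in 1508. Rises that were largest at 20 to 60 min included the transcription factor genes FOS and EGR1, and those largest at 480 min included the collagenase gene MMP1. The largest change came at 20 min in 208 rising and 71 falling genes, at 40 min in 101 and 94, at 60 min in 237 and 76, at 120 min in 571 and 135, at 240 min in 674 and 411, and at 480 min in 1271 and 721. The median change over all genes stayed between 0.02 and 0.05 at every time.

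**Figure D1:**
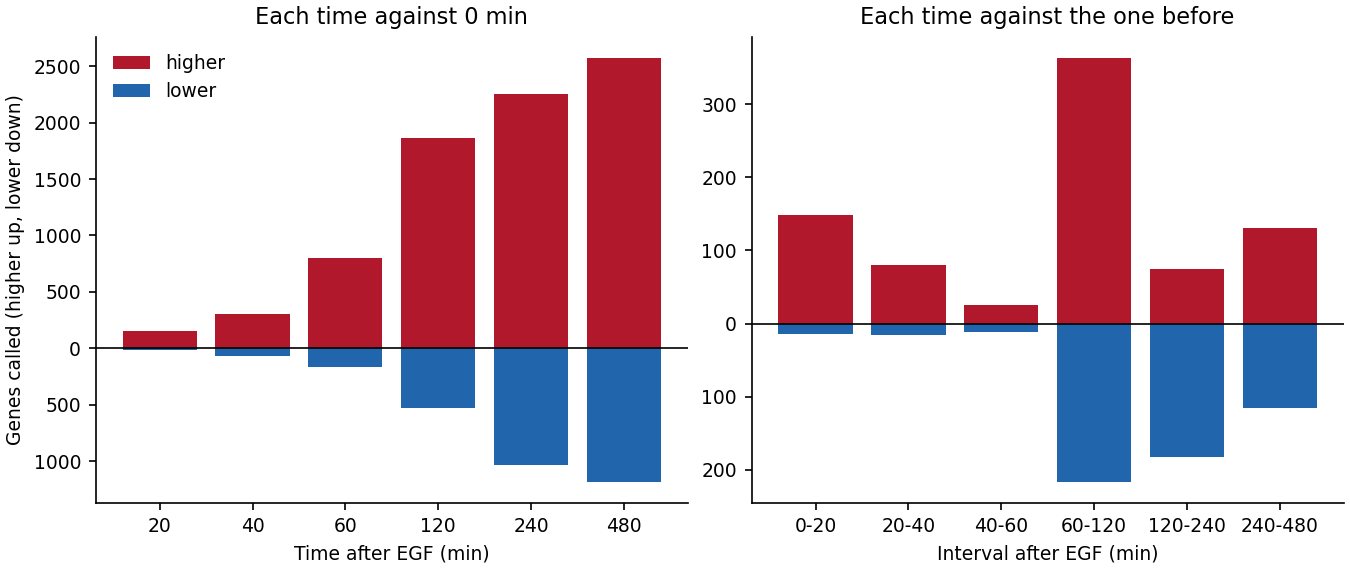
Numbers of genes called higher (bars above 0) and lower (bars below 0) by limma at each time against 0 min (left) and in each interval between successive times (right), in minutes after EGF, 3 arrays per time. Calls against 0 min went from 163 genes at 20 min to 3755 at 480 min, with more genes higher than lower at each time.

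At 20 min the largest rises were in FOS, which encodes a subunit of the transcription factor AP-1, by 4.31 ± 0.21 on the log2 scale (SE, n = 3 arrays per time), and in the orphan nuclear receptor gene NR4A1, by 3.27 ± 0.12. The phosphatase gene DUSP1, whose product inactivates MAP kinases, rose by 2.92 ± 0.13 and FOSB by 2.76 ± 0.12. The matricellular genes CCN1 and CCN2 rose by 2.43 ± 0.13 and 2.06 ± 0.15. EGR1, EGR2 and EGR3, zinc finger transcription factor genes, rose by 2.27 ± 0.13, 2.07 ± 0.17 and 2.23 ± 0.18. KLF6 rose by 2.15 ± 0.15, JUN by 1.99 ± 0.12 and IER2 by 1.93 ± 0.18. Adjusted p lay between 6.7e-14 for NR4A1 and 3.2e-07 for IER2 in these 12 genes. Falls were smaller and led by ONECUT1, a transcription factor gene, at -0.92 ± 0.19, adjusted p = 0.02. Next came RSPH1 at -0.74 ± 0.17, FAM86B1 at -0.74 ± 0.16 and EME1 at -0.63 ± 0.14 (0.05 without the filter on dim probesets). The other named falls were RGS19, SIX4, LIAT1, KRTAP5-9, PRSS54 and the noncoding RNA genes MEG3, SNHG6 and SNHG7, at between -0.60 for RGS19 and -0.48 for PRSS54.

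Of 30 measured immediate early transcription factors 21 rose at 20 min, 0 fell and 9 did not pass, or 25 and 0 when adjusted over the list alone (camera adjusted p = 2.1e-51). Of 25 feedback regulators of ERK and EGFR signalling 8 rose and 0 fell, 11 and 0 adjusted over the list alone (adjusted p = 4.1e-10). They included DUSP1, DUSP5 at 1.69 ± 0.13, DUSP6 at 1.18 ± 0.11 and DUSP4 at 0.81 ± 0.11. Chemokine, cytokine and NF-kB target genes held 8 rises and 0 falls in 23, 11 and 1 adjusted over the list alone (adjusted p = 2.3e-06). PTGS2, which encodes a prostaglandin synthase, stood at 1.92 ± 0.16, CXCL2 at 1.38 ± 0.14, NFKBIZ at 1.30 ± 0.16 and CXCL8 at 1.26 ± 0.19. Among 24 SRF and YAP targets 3 rose (CCN1, CCN2 and FHL2) and 0 fell, 8 and 0 adjusted over the list alone (adjusted p = 0.0032). The p53 list rose with 4 of 20 members (PLK2 at 0.91 ± 0.16, PMAIP1 at 0.97 ± 0.17, PLK3 at 0.57 ± 0.10 and CDKN1A at 0.50 ± 0.11), 8 and 0 adjusted over the list alone (adjusted p = 0.00071). PLK2 and PLK3 encode polo-like kinases.

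A further 5 lists were called higher at 20 min with few members past the test. Regulators of mRNA decay held 2 rises in 21, ZFP36, which encodes a protein that destabilises AU-rich mRNAs, at 1.84 ± 0.15 and ZC3H12A at 0.86 ± 0.12, 4 and 0 adjusted over the list alone (adjusted p = 0.012, and adjusted p = 0.25 with an estimated correlation). The EGF family list held 1 rise in 13, that of the ligand gene HBEGF at 1.70 ± 0.16, 2 adjusted over the list alone (adjusted p = 0.024, and adjusted p = 0.23 with an estimated correlation). FOXO and quiescence genes held 3 rises in 30 (CITED2 at 1.07 ± 0.10, YPEL5 at 0.72 ± 0.14 (-0.07 under the stricter filter) and GADD45A at 0.48 ± 0.11), 4 adjusted over the list alone (adjusted p = 0.024, and adjusted p = 0.39 with an estimated correlation). Basal and squamous markers held 2 rises in 20, SPRR2A at 1.67 ± 0.22 and IVL at 0.65 ± 0.13, both genes of the cornified envelope, with 7 adjusted over the list alone (adjusted p = 0.013, and adjusted p = 0.39 with an estimated correlation). The G2 and M phase list had 0 of 29 members past the test, 2 adjusted over the list alone, a median change of 0.23 and adjusted p = 0.012, with adjusted p = 0.57 with an estimated correlation.

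In all, 163 genes were called at 20 min, 149 higher and 14 lower, and 105 and 16 with the index covariate. The number depended on single arrays. It was 96, 95 and 81 without 0 min replicate 1, 20 min replicate 1 or 20 min replicate 2, 1176 without 20 min replicate 3 and 84 without the deviating array of each time. Of the 12 named falls 0 were called in every refit without 1 array of the times compared. Over 10 refits adjusted p ranged from 0.016 to 0.066 for the EGF family list, 0.011 to 0.29 for the FOXO list, 0.0037 to 0.79 for the G2 and M list and 0.00068 to 0.13 for the basal list.

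At 40 min FOS stood 29.6-fold above 0 min, with a log2 change of 4.89 ± 0.21, adjusted p = 7.3e-13 (SE, n = 3 arrays per time). NR4A1 rose by 4.16 ± 0.12, DUSP1 by 3.85 ± 0.13, EGR3 by 3.74 ± 0.18 and PTGS2 by 3.61 ± 0.16. FOSB rose by 3.49 ± 0.12 and HBEGF, a ligand of the EGF receptor, by 3.32 ± 0.16. The other large rises were EGR2 at 3.14 ± 0.17, DUSP5 at 2.78 ± 0.13, EGR1 at 2.73 ± 0.13, CCN2 at 2.68 ± 0.15 and the AP-1 subunit gene FOSL1 at 2.67 ± 0.14. AKR1C2, an aldo-keto reductase gene with near-identical relatives, fell by 1.11 ± 0.12, although only 2 of its 4 probesets moved that way. The gut peptide gene PYY was lower at -1.05 ± 0.23. C8orf44 at -0.89 ± 0.12, NAPB at -0.88 ± 0.16, PRXL2A at -0.80 ± 0.14 and the cold-inducible RNA-binding protein gene CIRBP at -0.74 ± 0.12, adjusted p = 0.00074 were also lower. The remaining named falls were SDHAP1 and FGF7P6, both named as pseudogenes, THOC3, UQCRB, GDF2 and TIGD3, from -0.83 for SDHAP1 to -0.72 for TIGD3.

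Immediate early transcription factors rose in 25 of 30 at 40 min with 0 falls, 27 and 0 adjusted over the list alone (adjusted p = 3.1e-89). Feedback regulators rose in 10 of 25 with 0 falls, 16 and 0 adjusted over the list alone (adjusted p = 6e-24). In the cytokine list 13 of 23 rose and 0 fell, 15 and 1 adjusted over the list alone (adjusted p = 6.1e-24). The rises included TNFAIP3, which encodes an inhibitor of NF-kB signalling, at 1.88 ± 0.11, the cytokine gene LIF at 2.48 ± 0.16, CXCL2 at 1.87 ± 0.14 and PTGS2. Proteolysis and migration genes rose in 8 of 29 with 0 falls, 11 and 1 adjusted over the list alone (adjusted p = 7.8e-12). PLAUR, the urokinase receptor gene, stood at 2.15 ± 0.10, the hyaluronan synthase gene HAS3 at 1.84 ± 0.11, PLAT at 0.60 ± 0.09 and VEGFA at 0.74 ± 0.11. SRF and YAP targets rose in 7 of 24 with 0 falls, 11 and 0 adjusted over the list alone (adjusted p = 7.8e-12). The focal adhesion gene VCL stood at 0.65 ± 0.11 and FHL2 at 0.68 ± 0.10. The p53 list had 5 rises in 20 (PLK3, PMAIP1, PLK2, ZMAT3 and SFN) and 0 falls, 7 and 1 adjusted over the list alone (adjusted p = 0.00016). PLK3 stood at 1.17 ± 0.10 and PMAIP1 at 1.12 ± 0.17.

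Markers of another cell type moved at the same time. Of 12 luminal markers FOXA1 rose by 0.81 ± 0.11 and GATA3 fell to -0.51 ± 0.10, 5 and 1 adjusted over the list alone, and the list was called higher (adjusted p = 0.0089). Basal and squamous markers rose in 3 of 20 (SPRR2A at 2.63 ± 0.22, IVL at 0.91 ± 0.13 and SFN at 0.43 ± 0.10), 5 and 0 adjusted over the list alone (adjusted p = 8.3e-06, and adjusted p = 0.086 with an estimated correlation). The EGF family list held HBEGF and EREG as 2 rises in 13, 3 adjusted over the list alone (adjusted p = 0.0051, and adjusted p = 0.088 with an estimated correlation). Glycolysis and supply genes held 3 rises in 27, SLC2A3 at 0.82 ± 0.16, PFKFB3 at 0.79 ± 0.12 and HK2 at 0.54 ± 0.14, and 3 adjusted over the list alone (adjusted p = 0.0051, and adjusted p = 0.16 with an estimated correlation). Regulators of mRNA decay held 3 rises in 21 (ZFP36 at 2.52 ± 0.15, ZC3H12A at 1.65 ± 0.12 and ZFP36L1 at 0.76 ± 0.11), 4 and 2 adjusted over the list alone (adjusted p = 0.014, and adjusted p = 0.21 with an estimated correlation). Cholesterol genes held 1 rise in 21, INSIG1 at 0.68 ± 0.15, 3 adjusted over the list alone (adjusted p = 0.047, and adjusted p = 0.46 with an estimated correlation). Ribosome biogenesis genes held 0 of 33, and 0 adjusted over the list alone (adjusted p = 0.032, and adjusted p = 0.55 with an estimated correlation).

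At 40 min 371 genes were called, 302 higher and 69 lower, but 440 higher and 243 lower with the index covariate. Of the 12 named falls 7 were called in every refit without 1 array (not GDF2, PYY, THOC3, TIGD3 and UQCRB). Over 10 refits adjusted p ranged from 0.0044 to 0.091 for the mRNA decay list, 0.022 to 0.25 for the cholesterol list and 0.0028 to 0.31 for the ribosome list.

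**Figure D2:**
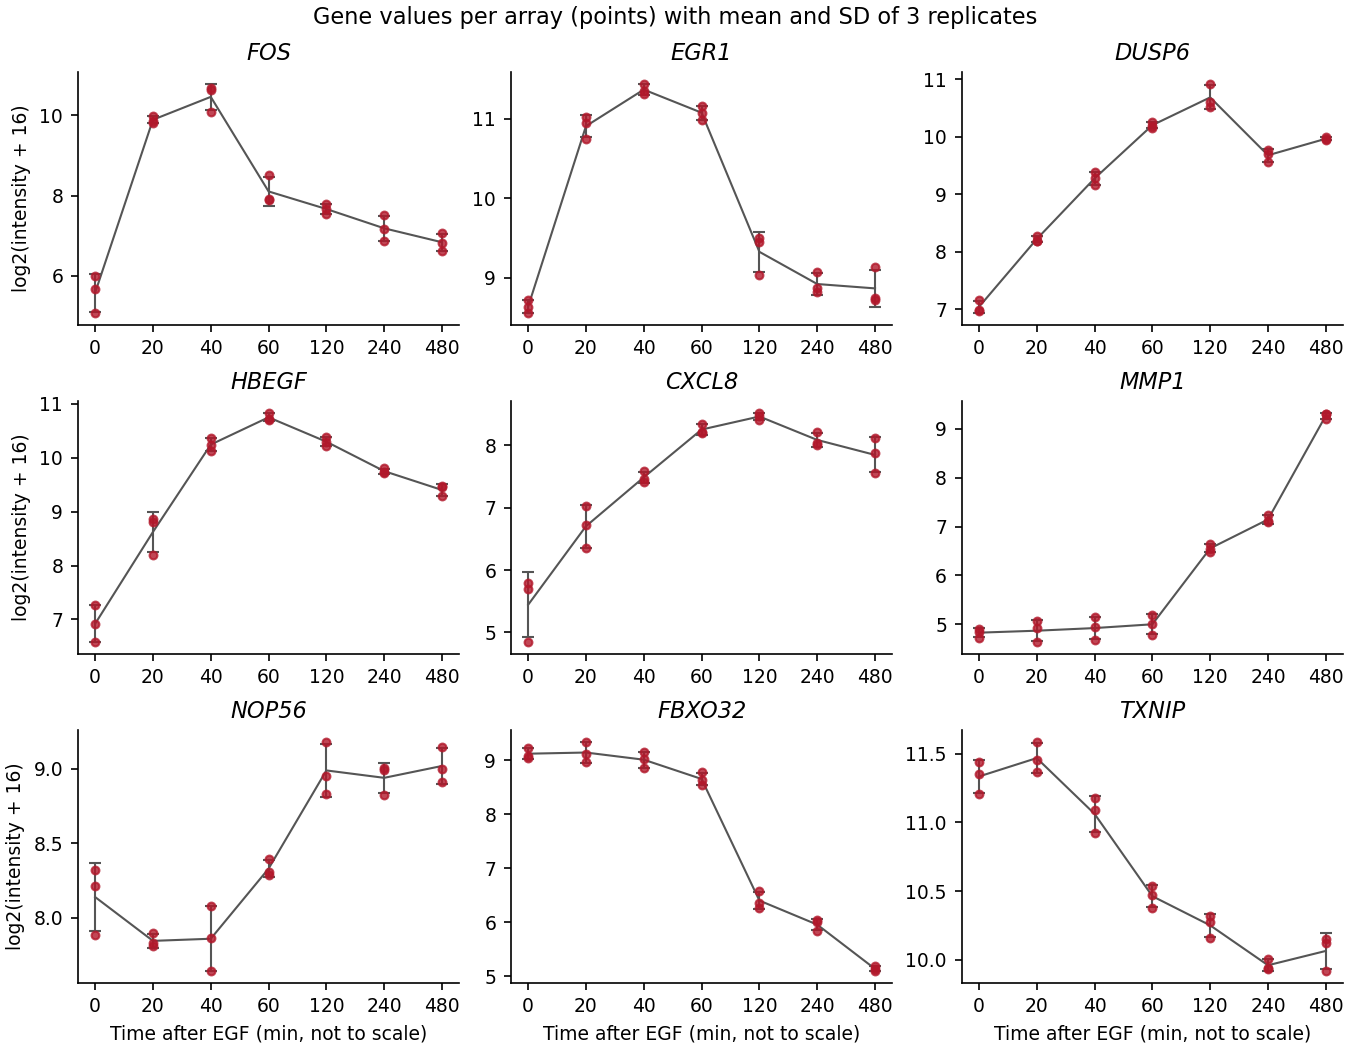
Log2(intensity + 16) of 9 genes on each of the 21 arrays (points, 3 per time) with the mean and SD per time, against minutes after EGF, spaced evenly and not to scale. FOS reached its highest mean at 40 min, DUSP6 at 120 min and MMP1 at 480 min, while FBXO32 had its lowest mean at 480 min.

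At 60 min NR4A1 was the most changed gene, 20-fold above 0 min at 4.32 ± 0.12, adjusted p = 2.2e-16 (SE, n = 3 arrays per time). It was followed by HBEGF at 3.83 ± 0.16, EGR3 at 3.79 ± 0.18, PTGS2 at 3.62 ± 0.16 and FOSB at 3.47 ± 0.12. DUSP6, which encodes a phosphatase specific for ERK, rose by 3.16 ± 0.11. LIF rose by 3.08 ± 0.16, SPRR2A by 3.0 ± 0.22 and CXCL8, the interleukin 8 gene, by 2.81 ± 0.19. EGR2, FOSL1 and DUSP5 completed the 12 largest rises at 2.89 ± 0.17, 2.82 ± 0.14 and 2.59 ± 0.13. The transcriptional repressor gene BCL6 fell to -1.05 ± 0.15, adjusted p = 6.5e-05, and CIRBP to -1.03 ± 0.12. The transcription factor gene GATA3 fell to -0.89 ± 0.10 and TXNIP, whose product binds thioredoxin, to -0.87 ± 0.10, adjusted p = 5.2e-06. MEAK7 was lower at -0.85 ± 0.13, FAM86B1 at -0.79 ± 0.16, TMEM138 at -0.78 ± 0.13 (0.08 under the stricter filter) and ZBED5 at -0.77 ± 0.12. ENPEP (0.06 without the filter on dim probesets), GUCA2B, the readthrough gene ANKHD1-EIF4EBP3 and the divergent transcript GATD1-DT completed the named falls, at -1.02 for GATD1-DT to -0.77 for GUCA2B.

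Of 30 immediate early transcription factors 25 rose at 60 min and 0 fell, 28 and 0 adjusted over the list alone (adjusted p = 3.2e-52), with NR4A1, FOSB, IER3 at 2.08 ± 0.09 and FOSL1 at the smallest adjusted p. Feedback regulators rose in 15 of 25 with 0 falls, 16 and 0 adjusted over the list alone (adjusted p = 2.7e-20). SPRY4, a Sprouty gene, stood at 2.50 ± 0.16 and ERRFI1, whose product inhibits the EGF receptor, at 1.91 ± 0.13. Cytokine and NF-kB genes rose in 16 of 23 with 0 falls, 20 and 2 adjusted over the list alone (adjusted p = 1.2e-23). TNFAIP3 stood at 2.49 ± 0.11. Proteolysis and migration genes rose in 15 of 29 with 0 falls, 19 and 0 adjusted over the list alone (adjusted p = 1e-17). HAS3 stood at 2.22 ± 0.11, PLAUR at 2.19 ± 0.10 and the urokinase gene PLAU at 1.09 ± 0.10. SRF and YAP targets rose in 9 of 24 with 0 falls, 11 and 0 adjusted over the list alone (adjusted p = 2.1e-08). VCL stood at 0.94 ± 0.11.

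EGF family genes rose in 5 of 13 at 60 min, and 5 adjusted over the list alone (adjusted p = 0.0011, and adjusted p = 0.068 with an estimated correlation). These were HBEGF, the ligand genes TGFA at 1.78 ± 0.15, EREG at 1.59 ± 0.14 and NRG1 at 0.52 ± 0.13, and ADAM17, which encodes a sheddase of these ligands, at 0.59 ± 0.14. Ribosome biogenesis genes rose in 10 of 33 with 0 falls, 19 and 0 adjusted over the list alone (adjusted p = 4.7e-07, and adjusted p = 0.15 with an estimated correlation). NIP7 stood at 0.82 ± 0.12 and UTP14A at 0.72 ± 0.15. Basal and squamous markers rose in 7 of 20 with 0 falls, and 7 adjusted over the list alone (adjusted p = 4.4e-05, and adjusted p = 0.14 with an estimated correlation). S100A2 stood at 0.98 ± 0.15. Regulators of mRNA decay rose in 6 of 21, 7 and 1 adjusted over the list alone (adjusted p = 0.0035, and adjusted p = 0.15 with an estimated correlation). ZFP36 stood at 1.79 ± 0.15 and ZFP36L2 at 0.92 ± 0.14. Cholesterol genes rose in 4 of 21 (HMGCS1 at 0.95 ± 0.16, INSIG1 at 0.95 ± 0.15, IDI1 at 1.05 ± 0.25 and STARD4 at 0.60 ± 0.18), 8 and 1 adjusted over the list alone (adjusted p = 0.0053, and adjusted p = 0.28 with an estimated correlation). Epithelial to mesenchymal transition factors rose in 4 of 21, and 4 adjusted over the list alone (adjusted p = 0.018, and adjusted p = 0.15 with an estimated correlation). These were the claudin gene CLDN4 at 1.58 ± 0.14, OVOL1 at 1.52 ± 0.14, OCLN at 0.91 ± 0.26 and INHBA at 0.50 ± 0.11, of which CLDN4 and OCLN encode tight junction proteins of epithelia and OVOL1 an epithelial transcription factor. Since the list mixes epithelial and mesenchymal genes, its calls at this and later times give no direction of the transition.

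At 60 min 963 genes were called, 801 higher and 162 lower, and 570 and 281 with the index covariate, and 607, 614 and 454 without 0 min replicate 1, 60 min replicate 1 or 60 min replicate 3. Of the 12 named falls 9 were called in every refit without 1 array (not ANKHD1-EIF4EBP3, GATD1-DT and GUCA2B).

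At 120 min DUSP6 stood 12.4-fold above 0 min at 3.64 ± 0.11, adjusted p = 1.2e-15 (SE, n = 3 arrays per time). HBEGF rose by 3.37 ± 0.16 and SPRY4 by 3.33 ± 0.16. The cytokine genes IL36G, LIF, IL33 and IL1B rose by 3.11 ± 0.23, 2.79 ± 0.16, 2.55 ± 0.17 and 2.50 ± 0.13. CXCL8 rose by 3.02 ± 0.19, the EGF family ligand gene EREG by 2.51 ± 0.14 and the phosphate transporter gene SLC20A1 by 2.49 ± 0.18. FOSL1 and SPRR2A were higher by 2.75 ± 0.14 and 2.52 ± 0.22. FBXO32, the ubiquitin ligase gene also known as atrogin-1 and a FOXO target in muscle, fell to -2.72 ± 0.12, adjusted p = 1.2e-12. VAV3, a guanine nucleotide exchange factor gene, fell to -1.92 ± 0.16. The kinase gene RIPK4 fell to -1.62 ± 0.12, ID3 to -1.42 ± 0.12, and SESN1, a sestrin gene, to -1.29 ± 0.23. SEMA6D fell to -1.25 ± 0.13, the pro-apoptotic gene BCL2L11 to -1.18 ± 0.15 and the arrestin family gene ARRDC4 to -1.09 ± 0.11. DLEU2L, NFIL3, TENT5B and SLC47A2 completed the falls, from -1.32 for DLEU2L to -1.12 for SLC47A2.

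Of 30 FOXO and quiescence genes 10 fell at 120 min and 2 rose. Adjusted over the list alone the counts were 11 and 2 (adjusted p = 3.1e-08, and adjusted p = 0.025 with an estimated correlation). The falls included ARRDC4, TXNIP at -1.08 ± 0.10 and PIK3IP1, whose product inhibits PI3 kinase, at -1.01 ± 0.12, and the rises were IRS1 at 1.21 ± 0.14 and GADD45A at 0.33 ± 0.11. Proteolysis and migration genes rose in 22 of 29 with 0 falls, 23 and 0 adjusted over the list alone (adjusted p = 5.8e-21). The integrin gene ITGA2 stood at 1.73 ± 0.17, HAS3 at 2.34 ± 0.11 and MMP1 at 1.72 ± 0.13. Cytokine and NF-kB genes rose in 18 of 23 with 0 falls, and 18 adjusted over the list alone (adjusted p = 8.2e-18). The chemokine gene CCL20 stood at 2.11 ± 0.13. Ribosome biogenesis genes rose in 25 of 33 with 0 falls. Adjusted over the list alone the counts were 27 and 0 (adjusted p = 9e-16, and adjusted p = 0.025 with an estimated correlation). POLR1C, which encodes a shared subunit of RNA polymerases I and III, stood at 0.97 ± 0.11, NIP7 at 0.94 ± 0.12 and RRP9 at 0.80 ± 0.10. Immediate early transcription factors rose in 20 of 30 and fell in 2, HES1 at -0.78 ± 0.12 and ELF3 at -0.60 ± 0.18, 21 and 2 adjusted over the list alone (adjusted p = 3.8e-14). Feedback regulators rose in 16 of 25 and fell in 1, NAB2 at -0.51 ± 0.10, with 16 and 1 adjusted over the list alone (adjusted p = 1.3e-12). The rises of the latter list included PHLDA1 at 2.25 ± 0.13 and DUSP7 at 1.72 ± 0.11.

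EGF family genes rose in 5 of 13 at 120 min (HBEGF, EREG, TGFA at 2.28 ± 0.15, NRG1 at 0.91 ± 0.13 and ADAM17 at 0.74 ± 0.14) and the receptor gene ERBB3 fell to -0.43 ± 0.10, 6 and 1 adjusted over the list alone (adjusted p = 0.002, and adjusted p = 0.063 with an estimated correlation). Basal and squamous markers rose in 9 of 20 and fell in 1, KRT15 at -0.33 ± 0.10, 10 and 1 adjusted over the list alone (adjusted p = 4e-04, and adjusted p = 0.16 with an estimated correlation). Epithelial to mesenchymal transition factors rose in 8 of 21 with 0 falls, and 8 adjusted over the list alone (adjusted p = 0.0043, and adjusted p = 0.063 with an estimated correlation). CLDN4 stood at 1.17 ± 0.14, INHBA at 0.83 ± 0.11, the transcription factor gene ZEB1 at 0.69 ± 0.10 and FST at 0.80 ± 0.14. SRF and YAP targets rose in 8 of 24 and fell in 2, AJUBA at -0.92 ± 0.10 and TPM1 at -0.49 ± 0.13, 10 and 2 adjusted over the list alone (adjusted p = 0.011). Luminal markers were not called (adjusted p = 0.17), with 5 rises (FOXA1 at 1.28 ± 0.11, XBP1, KRT18, KRT8 and TFF3) and the fall of GATA3 at -1.05 ± 0.10 in 12, and 5 and 1 adjusted over the list alone. The ID and BMP list was not called either (adjusted p = 0.16), with BMP2 at 1.00 ± 0.12 and BAMBI higher and ID3, GATA3 and BMP4 lower in 16, and 3 and 3 adjusted over the list alone.

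At 120 min 2395 genes were called, 1862 higher and 533 lower, and 1406 and 965 with the index covariate. There were 1561 called without 120 min replicate 3 and 1318 in a fit of only the 6 arrays compared. Adjusted p of the SRF and YAP list ranged from 0.0031 to 0.079 over 10 refits, with the highest without 120 min replicate 1, and that of the luminal list from 0.044 with the index covariate to 0.51.

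At 240 min SPRY4 stood 7.54-fold above 0 min at 2.91 ± 0.16, adjusted p = 2.9e-11 (SE, n = 3 arrays per time). The cytokine genes IL1B and IL33 rose by 2.87 ± 0.13 and 2.85 ± 0.17, and SPRR2A by 2.84 ± 0.22. HBEGF rose by 2.83 ± 0.16, CXCL8 by 2.64 ± 0.19 and DUSP6 by 2.63 ± 0.11. ODC1, for the first enzyme of polyamine synthesis, rose by 2.54 ± 0.13 and NT5E, for an ectonucleotidase, by 2.54 ± 0.19. LRAT, for a retinol esterifying enzyme, stood at 2.49 ± 0.15, AGPAT9, for a glycerolipid acyltransferase, at 2.39 ± 0.15 and FOSL1 at 2.42 ± 0.14. FBXO32 fell to -3.17 ± 0.12, adjusted p = 1.1e-13, FIBIN to -2.28 ± 0.24, the chemerin receptor gene CMKLR2 to -1.89 ± 0.15. VAV3 fell to -1.86 ± 0.16, ZSCAN31 to -1.83 ± 0.17 and the death-associated kinase gene DAPK1 to -1.8 ± 0.11. KLHL24, CYP1B1, BCL2L11, SESN3, ARRDC4 and SLC47A2 fell to between -1.64 for KLHL24 and -1.44 for SLC47A2.

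Ribosome biogenesis genes rose in 28 of 33 at 240 min with 0 falls. Adjusted over the list alone the counts were 29 and 0 (adjusted p = 3.6e-18, and adjusted p = 0.016 with an estimated correlation). RRP9 stood at 1.13 ± 0.10, NOP2 at 0.84 ± 0.10 and NIP7 at 1.00 ± 0.12. Proteolysis and migration genes rose in 23 of 29 and fell in 2, TNS3 at -0.86 ± 0.14 and MMP13 at -0.45 ± 0.14, with 23 and 2 adjusted over the list alone (adjusted p = 3.8e-17). FOXO and quiescence genes fell in 16 of 30 and rose in 1, IRS1 at 1.11 ± 0.14, 18 and 1 adjusted over the list alone (adjusted p = 3.3e-13). TXNIP stood at -1.37 ± 0.10 and the cell cycle inhibitor genes CDKN1B and CDKN1C at -0.80 ± 0.16 and -0.68 ± 0.13. Cytokine and NF-kB genes rose in 14 of 23 with 0 falls, and 14 adjusted over the list alone (adjusted p = 6.8e-09). Feedback regulators rose in 15 of 25 and fell in 3 (NAB2, NAB1 and LRIG1), 16 and 3 adjusted over the list alone (adjusted p = 7e-08), and NAB2 stood at -0.46 ± 0.10. SRF and YAP targets rose in 12 of 24, with VCL at 0.93 ± 0.11, ZYX at 0.92 ± 0.11 and ACTN1 at 0.76 ± 0.11, and fell in 2 (TPM1 and AJUBA), 13 and 2 adjusted over the list alone (adjusted p = 0.00064).

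Immediate early transcription factors rose in 11 of 30 at 240 min and fell in 2 (HES1 and ELF3), 13 and 2 adjusted over the list alone (adjusted p = 0.0071, and adjusted p = 0.29 with an estimated correlation). G2 and M phase genes were called lower, with 2 falls in 29, NUSAP1 at -0.60 ± 0.17 and TOP2A at -0.44 ± 0.13, and 2 adjusted over the list alone (adjusted p = 0.014, and adjusted p = 0.52 with an estimated correlation). Basal and squamous markers rose in 8 of 20 and fell in 1, KRT15 at -1.08 ± 0.10, 8 and 3 adjusted over the list alone (adjusted p = 0.016, and adjusted p = 0.36 with an estimated correlation). Epithelial to mesenchymal transition factors rose in 6 of 21, with FST at 1.04 ± 0.14, and 7 adjusted over the list alone (adjusted p = 0.02, and adjusted p = 0.18 with an estimated correlation). EGF family genes rose in 5 of 13 (HBEGF, TGFA, EREG, NRG1 and ADAM17) and ERBB3 fell to -0.48 ± 0.10, with 5 and 1 adjusted over the list alone (adjusted p = 0.023, and adjusted p = 0.22 with an estimated correlation). Cholesterol genes rose in 6 of 21, with HMGCS1 at 1.08 ± 0.16, and 7 adjusted over the list alone (adjusted p = 0.026, and adjusted p = 0.36 with an estimated correlation). G1 and S phase genes were not called (adjusted p = 0.29), with 5 higher (CDK6, CCND1, CCND3, CCNE1 and SLBP) and 6 lower in 34, 6 and 7 adjusted over the list alone, a median of -0.05 and a mean of 0.01. Here CDK6 rose by 1.08 ± 0.18 and CCND1, the cyclin D1 gene, by 0.56 ± 0.11, while CDC6 and CCNE2, of DNA replication licensing and cyclin E2, fell to -0.52 ± 0.17 and -0.59 ± 0.17.

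At 240 min 3281 genes were called, 2249 higher and 1032 lower, and 2109 and 1662 with the index covariate, with 2185 called without 240 min replicate 3. Over 10 refits adjusted p ranged from 0.013 to 0.086 for the EGF family list, 2.2e-06 to 0.064 for the G2 and M list, 0.0053 to 0.055 for the basal list and 0.0068 to 0.1 for the cholesterol list.

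At 480 min the matrix metalloproteinase gene MMP1 stood at the top, 21.7-fold above 0 min at 4.44 ± 0.13, adjusted p = 4.8e-16 (SE, n = 3 arrays per time). IL33 rose by 3.76 ± 0.17, MMP10, also a matrix metalloproteinase gene, by 3.72 ± 0.14 and NT5E by 3.36 ± 0.19. PLEK2, a pleckstrin gene, rose by 3.09 ± 0.15, SPRY4 by 2.93 ± 0.16 and DUSP6 by 2.92 ± 0.11. FERMT1, which encodes the integrin activator kindlin-1, rose by 2.74 ± 0.11. ODC1 rose by 2.64 ± 0.13, the protease inhibitor gene SERPINE2 by 2.58 ± 0.14, STC1 by 2.57 ± 0.15 and the acetylcholine receptor gene CHRNA9 by 2.57 ± 0.15. FBXO32 was 15.8-fold lower at -3.98 ± 0.12, adjusted p = 4.8e-16, and the basal keratin gene KRT15 4.85-fold lower at -2.28 ± 0.10, adjusted p = 1.1e-12. CMKLR2 fell to -2.05 ± 0.15, IGFBP3, which encodes a binding protein of insulin-like growth factors, to -1.97 ± 0.13. The transporter gene SLC47A2 fell to -1.88 ± 0.12 and the monoamine oxidase gene MAOA to -1.86 ± 0.11. ZSCAN31, FIBIN, ARRDC4, KLHL24, BCL2L11 and GABRE fell to between -1.86 for ZSCAN31 and -1.61 for GABRE.

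FOXO and quiescence genes fell in 20 of 30 at 480 min and IRS1 rose by 1.2 ± 0.14, 21 and 1 adjusted over the list alone (adjusted p = 4.7e-17), with a median of -0.68. PIK3IP1 stood at -1.30 ± 0.12, TXNIP at -1.27 ± 0.10, ARRDC4 at -1.76 ± 0.11 and KLHL24 at -1.67 ± 0.16. Ribosome biogenesis genes rose in 29 of 33 and NCL, the nucleolin gene, fell to -0.66 ± 0.22. Adjusted over the list alone the counts were 30 and 1 (adjusted p = 5e-16, and adjusted p = 0.032 with an estimated correlation). NOP2 stood at 0.93 ± 0.10, NOLC1 at 0.97 ± 0.11 and RRP9 at 0.98 ± 0.10. Proteolysis and migration genes rose in 23 of 29 and fell in 4 (TNS3 at -1.18 ± 0.14, MMP13, LAMA3 and TIMP3), with 23 and 4 adjusted over the list alone (adjusted p = 1.6e-15). Feedback regulators rose in 16 of 25 with 0 falls, 17 and 0 adjusted over the list alone (adjusted p = 2.9e-09). PHLDA1 stood at 2.32 ± 0.13 and DUSP4 at 1.83 ± 0.11. Cytokine and NF-kB genes rose in 12 of 23 with 0 falls. Adjusted over the list alone the counts were 13 and 0 (adjusted p = 1.3e-06, and adjusted p = 0.031 with an estimated correlation). IL24 stood at 2.02 ± 0.16.

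G1 and S phase genes rose in 13 of 34 at 480 min with 0 falls, 17 and 1 adjusted over the list alone (adjusted p = 0.00037, and adjusted p = 0.19 with an estimated correlation). CCND1 stood at 0.92 ± 0.11, CDC25A, a phosphatase gene that promotes S phase entry, at 0.76 ± 0.11, E2F7 at 0.69 ± 0.10 and CDK6 at 1.18 ± 0.18. G2 and M phase genes were called lower, with 5 falls in 29 (PTTG1, NUSAP1, TOP2A, KIF20A and MKI67) and the rise of AURKA at 0.46 ± 0.14, and 5 and 1 adjusted over the list alone (adjusted p = 0.024, and adjusted p = 0.57 with an estimated correlation). MKI67, the gene of the proliferation marker Ki-67, stood at -0.44 ± 0.13 and NUSAP1 at -0.62 ± 0.17. Cholesterol genes rose in 13 of 21 and fell in 2 (LSS and SREBF2), 14 and 2 adjusted over the list alone (adjusted p = 0.00037, and adjusted p = 0.17 with an estimated correlation). HMGCS1 stood at 1.28 ± 0.16, CYP51A1 at 0.85 ± 0.13 and SQLE at 0.96 ± 0.15, all enzymes of sterol synthesis. The p53 list was called lower, with 8 falls and 3 rises in 20, 8 and 5 adjusted over the list alone (adjusted p = 0.011, and adjusted p = 0.092 with an estimated correlation). TP53INP1 stood at -1.28 ± 0.13, XPC at -1.04 ± 0.13 and DDB2 at -0.65 ± 0.10, and the rises were PLK3, FAS and SFN. The glycolysis and supply list was not called (adjusted p = 0.18), with 11 rises in 27, among them the glucose transporter gene SLC2A3 at 1.92 ± 0.16 and the hexokinase gene HK2 at 1.06 ± 0.14, 2 falls (SLC7A5 at -0.58 ± 0.10 and SLC2A1 at -0.34 ± 0.09), and 11 and 2 adjusted over the list alone.

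The interferon list was called lower at 480 min, with 4 falls in 22 (STAT2 at -1.07 ± 0.13, IFIT1 at -1.31 ± 0.18, IFI44L at -0.85 ± 0.14 and IFI44) and OAS1 higher at 0.46 ± 0.13, and 4 and 1 adjusted over the list alone (adjusted p = 0.045, and adjusted p = 0.092 with an estimated correlation). Epithelial to mesenchymal transition factors rose in 5 of 21 (FST at 1.28 ± 0.14, ZEB1 at 0.74 ± 0.10, FN1 at 0.72 ± 0.14, INHBA at 0.65 ± 0.11 and VIM at 0.56 ± 0.11) and CLDN1 fell to -0.47 ± 0.14, with 5 and 1 adjusted over the list alone (adjusted p = 0.033, and adjusted p = 0.17 with an estimated correlation). Basal and squamous markers were not called (adjusted p = 0.058), with 8 rises in 20, among them S100A2 at 1.81 ± 0.15 and KRT6B at 1.29 ± 0.12, and the falls of KRT15 and DSC3, 9 and 2 adjusted over the list alone. Of 13 fibroblast markers FAP rose by 0.83 ± 0.19 and COL1A1 fell to -0.75 ± 0.12, with 1 and 1 adjusted over the list alone (adjusted p = 0.5), and the test pointed down while median and mean were 0.01. Luminal markers (adjusted p = 0.91) held 3 rises, XBP1 at 1.1 ± 0.12, KRT18 at 0.75 ± 0.11 and FOXA1 at 0.43 ± 0.11, and the fall of GATA3 at -1.02 ± 0.10 in 12, and 3 and 2 adjusted over the list alone. Of 13 reference genes TBP rose by 0.64 ± 0.22 and POLR2A fell to -0.38 ± 0.11, 2 and 1 adjusted over the list alone (adjusted p = 0.91).

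At 480 min 3755 genes were called, 2573 higher and 1182 lower, and 2544 and 1906 with the index covariate. Over 10 refits adjusted p ranged from 9.6e-06 to 0.11 for the G2 and M list, 0.029 to 0.067 for the transition factor list, 0.021 to 0.1 for the interferon list and 0.027 to 0.18 for the basal list, which was past the threshold in 4 of them.

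**Figure D3:**
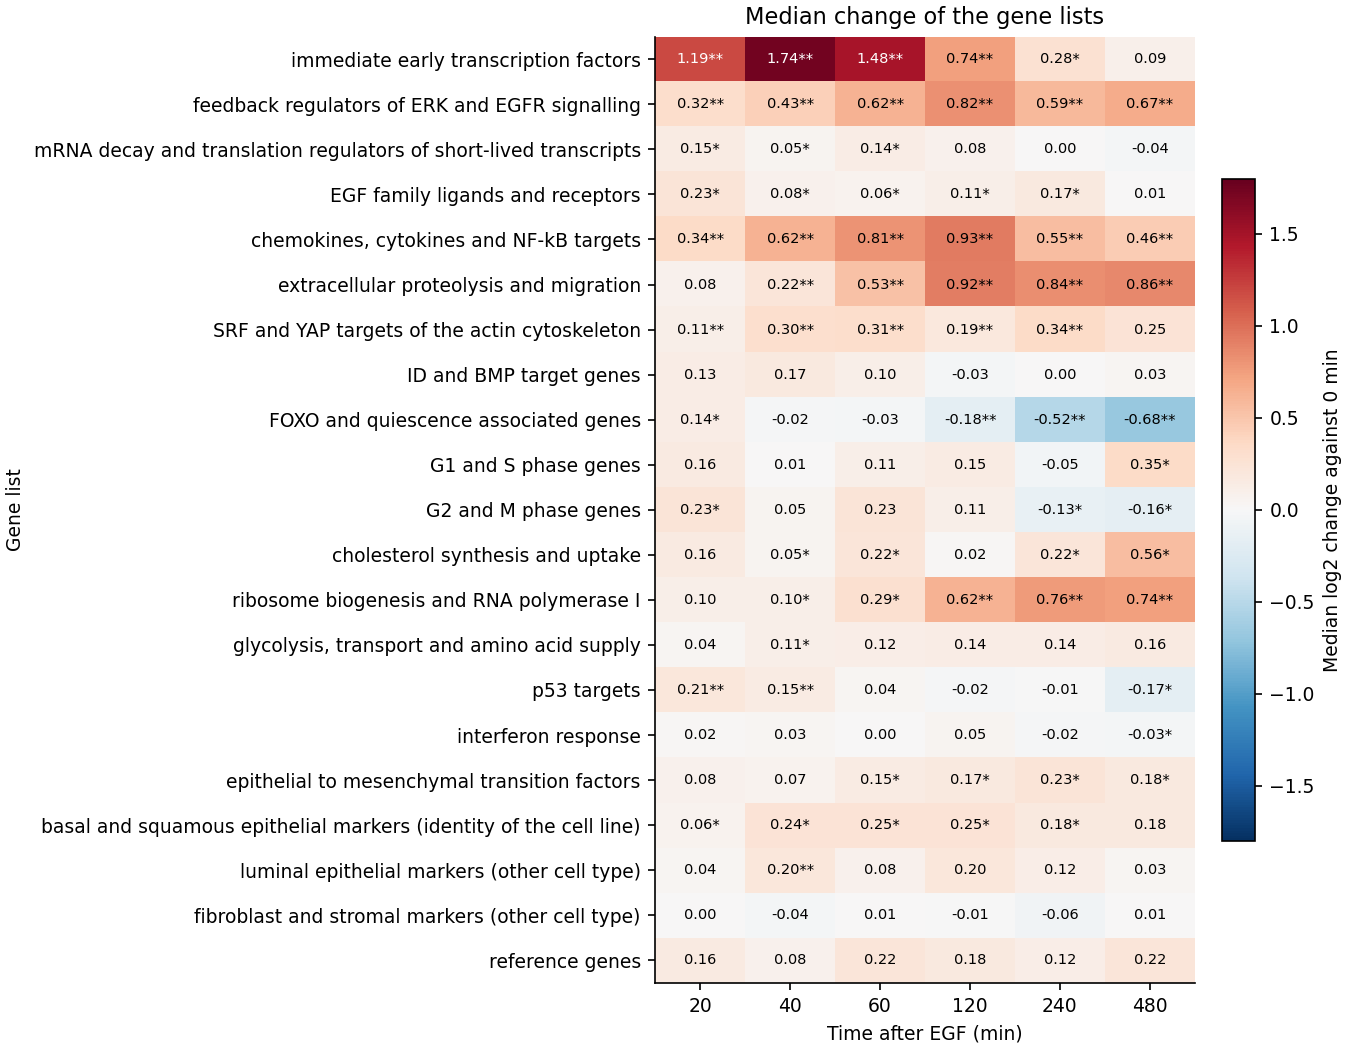
Median log2 change of each of the 21 lists at each time against 0 min in minutes (colour and number), with * where camera's adjusted p was under 0.05 at the preset correlation and ** where it was also under it with an estimated correlation. Immediate early transcription factors had their highest median, 1.74, at 40 min, while FOXO and quiescence genes had their lowest, -0.68, at 480 min.

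The contrasts between successive times ask in which interval transcripts changed. From 20 to 40 min 95 genes were called, 80 higher and 15 lower. LIF rose by a further 1.72 ± 0.16 (SE, n = 3 arrays per time), PTGS2 by 1.69 ± 0.16, FOSL1 by 1.64 ± 0.14, HBEGF by 1.62 ± 0.16 and EGR3 by 1.51 ± 0.18. ATF3, a stress-responsive transcription factor gene, fell back by 1.09. From 40 to 60 min 38 genes were called, 26 higher and 12 lower. FOS changed by -2.36 ± 0.21, adjusted p = 5e-06, DUSP1 by -1.27 ± 0.13, IER2 by -1.0 ± 0.18, BCL6 by -0.88 ± 0.15 and JUN by -0.87 ± 0.12. SPRY4 rose by 1.21 ± 0.15 and DUSP6 by 0.93 ± 0.11. From 60 to 120 min 579 genes were called, 363 higher and 216 lower. NR4A1 changed by -3.17 ± 0.12, EGR2 by -2.38 ± 0.17, FBXO32 by -2.25 ± 0.12, PTGS2 by -1.98 ± 0.16, FOSB by -1.93 ± 0.12 and EGR1 by -1.75 ± 0.13. IL33 rose by 2.06 ± 0.17 and MMP1 by 1.55 ± 0.13.

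From 120 to 240 min 256 genes were called, 74 higher and 182 lower. NR4A3 changed by -1.68 ± 0.14, EGR3 by -1.59 ± 0.18 and FOSB by -1.44 ± 0.12. The antiproliferative gene BTG2 rose by 0.73 ± 0.14 and NT5E by 0.91 ± 0.19. From 240 to 480 min 245 genes were called, 130 higher and 115 lower. MMP1 rose by a further 2.12 ± 0.13, MMP10 by 2.0 ± 0.14, and the replication genes DTL, CCNE2 and CDC6 by 1.77 ± 0.19, 1.42 ± 0.17 and 1.35 ± 0.17. KRT15 changed by -1.20 ± 0.10 and IGFBP3 by -1.30 ± 0.14. With the index covariate the 5 intervals had 124 higher and 25 lower, 39 and 18, 635 and 494, 224 and 279, and 289 and 346, so that the last turned to more falls. Without 1 array of the times compared the counts lay between 58 and 324, 12 and 34, 383 and 546, 124 and 248, and 127 and 186. From 40 to 60 min 221 (178 higher and 43 lower) were called without the deviating array of each time and 71 with the mean of probesets. Of the counts without 1 array 324 (169 higher and 155 lower) was reached without 20 min replicate 3, 58 without 40 min replicate 3 and 12 without 60 min replicate 3. More genes were lower than higher from 60 to 120 min without 120 min replicate 3 (216 higher and 254 lower) and from 240 to 480 min without 240 min replicate 1 (62 and 76) or 480 min replicate 3 (57 and 70). With a change of at least 2-fold 28 were higher and 37 lower from 60 to 120 min and 12 and 13 from 240 to 480 min, where the stricter filter gave 143 and 152 and a fit of only the 6 arrays compared 105 and 105.

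Of 5130 genes called at 1 or more times, 54 were called higher at some time and lower at another. Some of these changes were small, such as those of ZNRF2, at 0.33 at 60 min and -0.30 at 480 min. In FILIP1L, RPS24, PANK1 and SLC9A9 a called change turned its sign, uncalled, under another filter on dim probesets. The Notch target gene HES1 rose by 1.15 ± 0.12 (SE, n = 3) at 40 min and stood at -0.78 ± 0.12 at 120 min. CITED2, a transcriptional coregulator gene, rose by 1.07 ± 0.10 at 20 min and fell to -0.68 ± 0.10 at 480 min. The kinase gene MAP3K8 rose by 1.34 ± 0.14 at 60 min and stood at -0.63 ± 0.14 at 480 min. SIK1 rose by 1.17 ± 0.11 at 40 min and stood at -0.49 ± 0.11 at 120 min, and PLK2 went from 1.00 ± 0.16 at 40 min to -0.52 ± 0.16 at 120 min. The opposite order was seen in the replication genes CDC6, CCNE2 and DTL, at -0.52 ± 0.17, -0.59 ± 0.17 and -0.77 ± 0.19 at 240 min and 0.83 ± 0.17, 0.83 ± 0.17 and 1.00 ± 0.19 at 480 min. Calls at one time against calls at another were compared through the same 0 min arrays, and no overlap was tested.

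**Figure D4:**
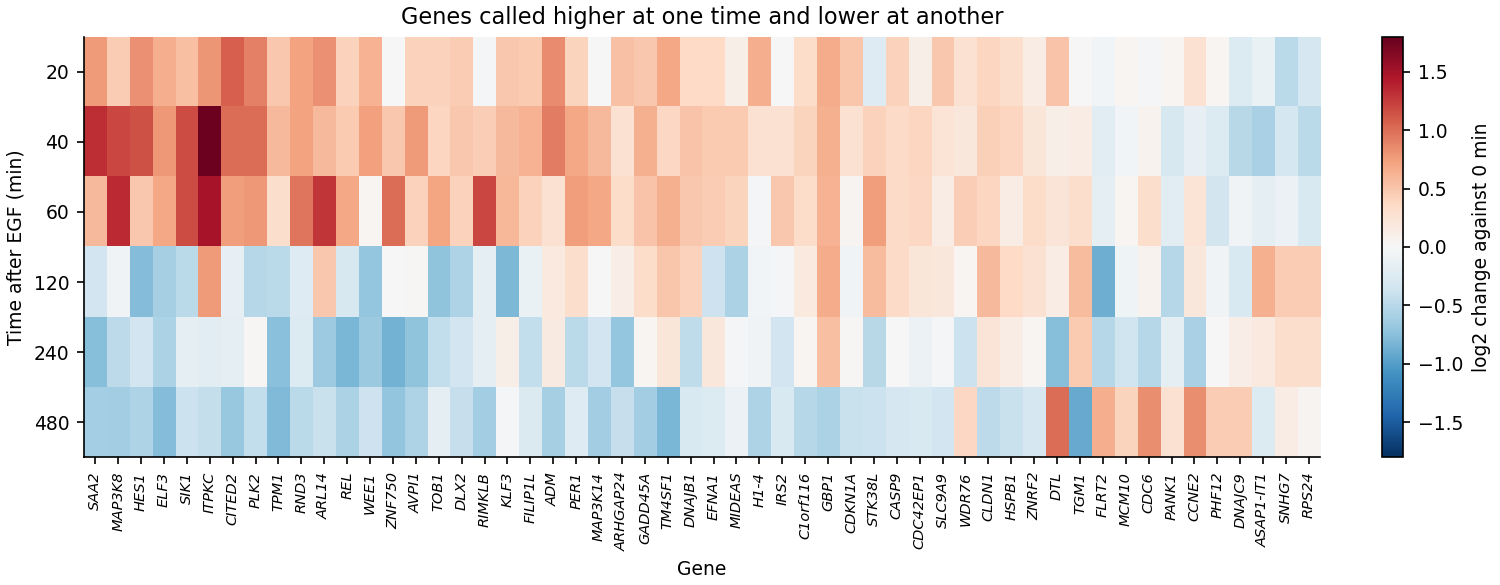
Log2 change against 0 min of the 54 genes called higher at some time and lower at another (genes against minutes after EGF, red higher and blue lower, 3 arrays per time). HES1 went from 1.15 at 40 min to -0.78 at 120 min and DTL from -0.77 at 240 min to 1.00 at 480 min.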

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

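All tests on the unnamed probesets in this part were chosen after the result was seen. Probesets that the annotation leaves unnamed entered no comparison of genes, and many of them changed after EGF. Of 420418 such probesets at or above the median level, limma called 2700 at 20 min, 7864 at 40 min, 13525 at 60 min, 16317 at 120 min, 13909 at 240 min and 16013 at 480 min. They were more often higher than lower at 20 min (2386 and 314) and at 60 min (8328 and 5197), and more often lower at 480 min (6891 and 9122). With the array index as a covariate they were about as often higher as lower at 60 min (5352 and 5474), more often lower at 120 min (8168 and 9777, against 8896 and 7421 without it), and 13283 were called at 40 min and 27817 at 480 min. The counts also depended on single arrays of 0, 60 and 480 min, the only ones left out for them. At 60 min they lay between 6062 (without 60 min replicate 3) and 14476 (without 480 min replicate 2), and at 480 min between 7974 (without 480 min replicate 3) and 16630 (without 0 min replicate 1). Of 261183 single-gene probesets 1288, 3671, 9004, 19513, 26089 and 31610 were called at the same times.

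The unnamed probesets had 0.845 calls at 60 min per call at 480 min against 0.285 for single-gene probesets, a ratio of 2.97. At 60 min 3.22% of unnamed and 3.45% of single-gene probesets were called, and at 480 min 3.81% and 12.1%. The ratio thus came from a smaller called share of unnamed probesets at 480 min, not from a larger one at 60 min. At 20 and 40 min the shares were 0.642% and 1.87% of unnamed against 0.493% and 1.41% of single-gene probesets. The ratio stayed between 2.55 and 3.6 without any 1 array of 0, 60 and 480 min. Its unnamed part moved between 0.386 (without 60 min replicate 3) and 1.55 (without 480 min replicate 3). Its single-gene part moved between 0.125 and 0.462 without the same arrays. The lower signal of the unnamed probesets is argued against as the whole cause, since within 4 bands of mean level the ratio lay between 2.06 and 2.89. The bands were cut at the quartiles of mean level, so levels could still differ inside a band. Each band's ratio lay below 2.97, so part of it may go with level. With the index as a covariate the ratio was 2.18 (0.389 and 0.178). The index is built from the same classes of probesets, and its mean was higher at every EGF time than at 0 min. The covariate therefore cannot decide whether differences between arrays in the index are the cause. Unspliced transcripts among the unnamed probesets are a candidate explanation. It cannot be told apart from other early transcribed sequence, or from whatever kept late calls few, because no probeset positions were used. The ratio of 2.97 alone decides nothing. No other biological explanation was tested.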

How the results depend on the processing

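The fits with the array index as a covariate and without the deviating array of each time, and leaving out arrays for the lists, were chosen after the result was seen. The comparisons of intronic signal and their alternatives were not run. Of 606 called changes of named genes 604 kept direction and call under quantile normalisation, 605 under median centring, 585 and 588 with pseudocounts of 1 and 64, 602 with a trended robust variance, 559 with the mean of probesets, 565 with the index covariate, 510 without the deviating arrays and 515 with only the 6 arrays compared. Of 288 uncalled changes of named genes between 0 (median centring) and 66 (mean of probesets) became called in the same direction. Of 67 called list results 67 kept their call under quantile normalisation, 62 with fry, 35 with an estimated correlation, 58 with the index covariate and 58 without the deviating arrays. Fry also called 21 of the 59 list results not called. It asks whether a list changed at all, camera whether it changed more than other genes, so its kept calls are weak support. Quantile normalisation tests little, since array medians differed from the common value by at most 0.004. Leaving out each array of the times compared kept 3140 of 3636 gene calls and 375 of 402 list calls, with fewer samples in each fit and the remaining pair assumed to vary like the other times.

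Reversed values were few. Without the filter EME1 at 20 min stood at 0.05, ENPEP at 60 min at 0.059, FILIP1L at 240 min at 0.143 and RPS24 at 40 min at 0.051, and with the stricter filter TMEM138 at 60 min at 0.082. The stricter filter also gave -0.181 for PANK1 at 480 min against 0 min, -0.067 for SLC9A9 at 20 min against 0 min and -0.068 for YPEL5 at 20 min against 0 min. None of these 8 was called there, 537 of 606 and 510 of 570 named calls were kept, and the cause was not tested. CDKN1A at 120 min against 0 min was higher by 0.371 with the mean of probesets (not called at -0.06 with the median), and the G2 and M list at 120 min was called lower with the index covariate (adjusted p = 0.031, range 0.031 to 0.85 over 10 refits).

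Counts moved by over 1.5 times as follows, and apart from thresholds and sample numbers the cause was not tested. At 0.01 the times had 77, 223, 447, 1354, 1898 and 2301 genes, the F-test 2907 and the intervals 53, 16, 310, 135 and 114. With a change of at least 2-fold they had 45, 91, 155, 290, 383 and 405, the F-test 673 and the intervals 18, 6, 65, 25 and 25. With an estimated correlation 5, 7, 5, 6 and 5 lists were called at 20, 40, 60, 240 and 480 min. The mean of probesets gave 187, 71, 895, 459 and 458 genes in the intervals. The index covariate gave 683 at 40 min and 149, 1129, 503 and 635 in the intervals from 20, 60, 120 and 240 min. Without the deviating arrays 84 genes were called at 20 min and 51, 221 and 160 in the intervals from 20, 40 and 120 min. With only the 6 arrays compared 74 were called at 20 min, 1318 at 120 min and 40, 253 and 119 in the intervals from 20, 60 and 120 min.

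Without 1 array of the times compared the counts ranged from 81 to 1176 at 20 min, 256 to 305 at 40 min, 454 to 1006 at 60 min, 1561 to 3044 at 120 min, 2185 to 2779 at 240 min, 2658 to 3789 at 480 min and 3730 to 5217 for the F-test. The intervals ranged from 58 to 324, 12 to 34, 383 to 546, 124 to 248 and 127 to 186, and called lists from 8 to 12, 10 to 14, 11 to 13, 9 to 10, 9 to 12 and 8 to 13. Counts at 20 min were 96, 95, 81 and 1176 without 0 min replicate 1 or 20 min replicates 1, 2 or 3, and at 60 min 607, 614 and 454 without 0 min replicate 1 or 60 min replicates 1 or 3. At 120 min 1561 were called without 120 min replicate 3 and at 240 min 2185 without 240 min replicate 3. From 20 to 40 min the counts were 62 and 324 without 20 min replicates 1 or 3 and 62 and 58 without 40 min replicates 2 or 3. From 40 to 60 min they were 14 and 18 without 40 min replicates 2 or 3 and 22 and 12 without 60 min replicates 1 or 3. From 60 to 120 min 383 were called without 120 min replicate 2. From 120 to 240 min they were 154 without 120 min replicate 3 and 124, 150 and 162 without 240 min replicates 1, 2 or 3. From 240 to 480 min they were 138, 127 and 133 without 240 min replicates 1, 2 or 3 and 136 and 127 without 480 min replicates 1 or 3.

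Whether arrays with the same replicate letter belong to 1 time course is not given in the sources used here and was not settled by the values. Of 63 same-letter pairs of arrays 19 deviated together with a correlation above 0.1 (range -0.541 to 0.565), and 11 of 21 arrays correlated best with their own letter. The median correlation was -0.0111 for the same-letter pairs and 0.00747 for the 126 pairs with different letters, so at the median same-letter arrays did not deviate together. Pairs with different letters were more numerous, however, so 11 of 21 best matches is more than letters without meaning would give on average. Whether this excess is beyond chance was not tested. With the letter as a replicate block 148, 331, 925, 2297, 3136 and 3634 genes were called at the 6 times, 4305 by the F-test and 85, 30, 531, 219 and 214 in the intervals, 26 of 606 named gene calls were lost, 2 of 288 were gained, and no list call changed.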

Other observations

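The test with the array index for the share of higher genes was chosen after the result was seen, and the genes of the first 2 paragraphs were named after their values had been seen. Several regulators turned over within the first 120 min. The transcription factor gene ELF3 rose by 0.78 ± 0.18 (SE, n = 3 arrays per time) at 40 min and stood at -0.60 ± 0.18 at 120 min. KLF3 went from 0.60 ± 0.12 at 60 min to -0.81 ± 0.12 at 120 min, TOB1, an antiproliferative gene, from 0.71 ± 0.20 to -0.73 ± 0.20, and WEE1, which encodes an inhibitory kinase of the mitotic cyclin-dependent kinase, from 0.74 ± 0.13 at 40 min to -0.69 ± 0.13 at 120 min. ZNF750, an epidermal differentiation factor gene, rose by 1.01 ± 0.15 at 60 min and stood at -0.85 ± 0.15 at 240 min. The transglutaminase gene TGM1 was higher at 120 min by 0.57 ± 0.12 and lower at 480 min at -0.91 ± 0.12.

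The receptor genes EGFR and ERBB2 did not pass at any time. EGFR stood at 0.28 ± 0.12, adjusted p = 0.11 and ERBB2 at -0.27 ± 0.11, adjusted p = 0.094 at 480 min, while ERBB3 was called lower from 120 min, at -0.43 ± 0.10 at 480 min. The ligand gene EPGN was lower at 480 min at -1.06 ± 0.28. Of 21 regulators of mRNA decay 7 rose at 120 min, among them ZFP36L2 at 1.04 ± 0.14 and TOB2 at 0.92 ± 0.12, and 3 fell, BTG2 at -0.79 ± 0.14, TOB1 and HNRNPD, 7 and 4 adjusted over the list alone (camera adjusted p = 0.37). The p53 list at 120 min held 5 rises and 7 falls in 20, 6 and 8 adjusted over the list alone (adjusted p = 0.19), with PLK3 at 1.09 ± 0.10, FAS at 0.74 ± 0.14, PMAIP1, SFN and TNFRSF10B higher and MDM2 at -0.45 ± 0.13 lower.

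Medians, means and the test differed in sign for 11 results of lists, 2 of them given above and none called. FOXO genes at 40 min had -0.02, 0.02 and down, and regulators of mRNA decay at 480 min -0.04, 0.07 and down. Fibroblast markers had a mean of 0.04 at 20 min, 0.03 at 40 min and 0.04 at 60 min against a test that pointed down. So did G1 and S phase genes with 0.02 at 40 min, interferon genes with 0.05 at 60 min and 0.05 at 120 min, and ID and BMP targets with 0.03 at 480 min.

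More genes were called higher than lower at each time, with 68.5% of calls higher at 240 and 480 min. With the index as a covariate the lowest share over the 6 times was 55.9%, and 55.4% at the lowest without any 1 array. Among genes past the F-test in that fit the largest change was a rise in 54.9%. Of single-gene probesets 18553 were called higher and 17695 lower at 480 min with the covariate, the most even of the 6 times. The covariate lowered the share of higher genes at every time, from 91.4, 81.4, 83.2, 77.7, 68.5 and 68.5% to 86.8, 64.4, 67, 59.3, 55.9 and 57.2%. The index uses the single-gene probesets themselves, and its mean was higher at every EGF time than at 0 min. The covariate therefore cannot tell array differences from an effect of EGF, and differences between arrays stay open as a cause. Scaling between arrays cannot be told apart from a true excess of rises, because the arrays had been equalised before deposit and quantile normalisation or median centring, which left a lowest share of 68.3%, moved array medians by at most 0.004. That EGF raised more transcripts than it lowered stays open as a biological explanation. It cannot be told apart from effects of handling or time in culture, because untreated arrays were present only at 0 min.

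Genes whose largest change was a rise at 20 to 60 min had a median of 15 probesets on the array and those with the largest rise at 240 or 480 min 19, a difference of -4 (546 and 1945 genes, permutation p = 1e-05, the smallest that 1e+05 permutations can give, 2e-05 after Benjamini-Hochberg adjustment over 4 comparisons). Among rises of at least 2-fold the medians were 13 and 17 (107 and 326 genes, permutation p = 0.0015, adjusted 0.002). Shorter genes responding first is a candidate explanation, though gene length was not measured and the number of probesets only stands in for it. However, largest falls at the same times differed by -7 (medians 14 and 21, 241 and 1132 genes, permutation p = 1e-05, adjusted 2e-05), as noise in genes with few probesets would also give. Falls of at least 2-fold, 4 early and 106 late, had medians of 7 and 19 (permutation p = 0.098). Both explanations stay open, and genes are not independent replicates.

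Other splits of the arrays were compared with the real one. The F-test gave 4570 genes for the real assignment of times and at most 573 in the other splits of 100. Thus 1 of 100 splits, the real one, gave as many, the smallest share that 100 splits can give. This argues against chance for the total, but says nothing about single genes, since other splits had up to 573 calls. Each pair of times has 10 splits, too few for a share under 0.05, and 1 of 10, the real one, gave as many calls in each contrast. Against 0 min the real count and the highest other were 163 and 59 at 20 min, 371 and 1 at 40 min, 963 and 0 at 60 min, 2395 and 0 at 120 min, 3281 and 0 at 240 min and 3755 and 0 at 480 min. For the successive intervals they were 95 and 0, 38 and 0, 579 and 0, 256 and 0, and 245 and 1. For the lists they were 10 and 7, 13 and 10, 11 and 8, 10 and 9, 12 and 10, and 11 and 9. The other splits thus called nearly as many lists as the real times. Their groups still held unequal numbers of treated and untreated arrays, so part of a real change could remain in them. Whether this or a too low preset correlation gave their list calls was not tested. List counts therefore decide little, and list calls that rest on the preset correlation alone stay uncertain.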
